A study of Mus musculus with 5 samples.

How the data were processed

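ChIP-seq libraries were made from enriched pachytene and diplotene spermatocytes of adult C57BL/6 mice, cross-linked with 1% formaldehyde, per the labels' protocols. The labels place the 5 samples in 3 groups: wild-type input (replicates 1 and 2), wild-type ChIP for ZFP541 (replicates 1 and 2) and knockout ChIP for ZFP541 (1 library). Peak lists of the 3 ChIP libraries were used, and the inputs were not analysed here. Per the submitters' processing notes, cutadapt 2.6, Bowtie2 2.3.5, SAMtools 1.10, Picard, MACS2 2.2.6 and deepTools 3.5.0 were used with the mm10 build; their settings, the control of each peak call and the peak threshold are not given in the sources used here.

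Each deposited list holds 1 library's peaks, so replicates were called separately. The deposited lists give for each peak a fold enrichment (a ratio over the caller's background), −log10 p, −log10 q, the offset of the summit and a score that equals the −log10 q times 10 without its decimals at every peak. These values are the authors' own and were used to describe, rank or filter peaks. The ratio of −log10 p to fold was also compared between sets of peaks, for the knockout peaks only. The lists reach beyond a q-value of 0.05: 1580 peaks (19.2%) of replicate 1, 2349 (22.6%) of replicate 2 and 29 (11.3%) of the knockout have a higher q-value. The lowest −log10 p was 2.71, 2.54 and 4.47 in that order, so the knockout list began at a stricter value. Numbers of peaks depend on read depth, which is unknown here.

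Peaks sharing at least 1 bp were counted as overlapping. Overlapping wild-type peaks of the replicates were joined into regions, regions with a knockout peak were removed, and the summit was that of the replicate 1 peak with the highest fold. Random expectations came from 1000 seeded placements with the same widths on the same chromosome, between the first and last base covered by a gene or peak, with one-sided empirical p-values whose smallest value is 0.001. Intervals of shares are 95% exact (Clopper-Pearson) and cover counting error only.

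Genes came from a RefSeq table of GRCm38.p6, the assembly of mm10, which gives the start and end of each gene without strand, exons or sequence. The design called for windows around transcription start sites, exon and intron classes, CpG content, enriched short sequences and matching of lists on CpG density. Windows within 1 kb of either gene end were used in place of start sites, and random lists were matched on deciles of gene length in place of CpG density. The other analyses were not run. On autosomes and X, 340 gene entries (108 protein-coding) that lie before 3 Mb, where these chromosomes begin with an unsequenced gap, carry scaffold coordinates and were left out. That step was added after list results with those entries had been seen, and it moved 1 list, pachytene regulators, across the threshold.

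A protein-coding gene was occupied if a region overlapped the window within 1 kb of either end. The 16 gene lists, of 15 to 42 genes, were fixed before the data were examined, as were the tests, most alternatives and the genes to name. All 406 list names were matched, 5 of them through a synonym, to 401 distinct genes; Zfp541 and Kctd19 are in both the complex list and the pachytene list. Named were Zfp541, Kctd19, Hdac1 and Hdac2, up to 4 occupied members of each list and 10 genes overall with the best mean percentile rank of fold, the 5 best regions away from gene ends and the 5 knockout peaks with the highest fold. Of the genes this rule names, 1 is not reported here. The X-linked examples Lonrf3, Suv39h1, Rbbp7 and Taf7l were chosen after their values were seen. Lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over the 16 lists, and X-linked with autosomal genes by the same test without adjustment. Odds ratios have conditional exact intervals.

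Alternatives covered stricter q-values, a reciprocal overlap of 50%, summit overlap, each wild-type replicate alone, knockout peaks kept, windows of 500 bp and 2 kb, and placement over all chromosomes. Chosen after seeing the data were the −log10 p of the knockout list as a minimum, placement at gene ends, and leaving out chromosome starts, clustered gene families or genes with shared windows. Keeping the scaffold entries was also chosen then. Clustered families are 31 groups of at least 20 genes with a common symbol stem of which at least 50% lie within 500 kb of another member. A common stem, such as Gm with 1323 of their 4109 genes, need not mean related genes.

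Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The overlap step was tested on simulated data in which 50.6% of 8236 intervals were copied, and it found 50.8%. For the list test, simulated occupancy was drawn independently for each gene at a common share. The test called 4% of random lists of 40 genes at an unadjusted p under 0.05. It called 99% of such lists when their occupancy was drawn at 55%, the share seen for histone modifiers. Clustered families, shared windows, smaller lists and the adjustment were not simulated, so these shares do not give the power for other lists.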

Results

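ZFP541, a zinc finger protein of male germ cells, was mapped on the genome of pachytene and diplotene spermatocytes by ChIP-seq, in which cross-linked chromatin is enriched with an antibody and the DNA is sequenced. The cells came from testes of adult C57BL/6 mice and were enriched by STA-PUT, a sedimentation method that separates germ cells by size. Of 5 samples, 2 were wild-type ChIP libraries with an antibody against ZFP541, 1 was a ChIP library with the same antibody from Zfp541 knockout cells, and 2 were wild-type input libraries, for which no peak lists were analysed here. The wild-type lists held 8236 peaks in replicate 1 and 10371 in replicate 2, with median widths of 454.5 bp and 472 bp and covered lengths of 5.50 Mb and 7.66 Mb. The knockout list held 256 peaks with a median width of 337.5 bp, covering 0.129 Mb. The median fold enrichment that the authors' peak caller gave was 4.29 in replicate 1, 4.03 in replicate 2 and 3.33 in the knockout. Read depth is unknown from these lists, so a missing peak is not evidence that a site was unbound, and nothing in the labels says whether the replicates came from separate animals.

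The knockout comparison asks which peaks depend on ZFP541. At the Zfp541 gene itself (chromosome 7, 16061775 to 16096340, mm10), both wild-type libraries had a peak at the lower-coordinate end of the gene, with fold enrichments of 18.6 and 22.2, and the knockout library had none. This is the gene altered in the knockout, and whether its sequence at this end was changed was not examined. The locus alone therefore does not show that the peak depends on ZFP541. Wild-type lists were 32.2 and 40.5 times as long as the knockout list. When only peaks with at least the lowest −log10 p in the knockout list, 4.47, were counted, 6604 and 6919 wild-type peaks stood against 256, which is 25.8 and 27.0 times as many. A knockout peak overlapped 1.93% of replicate 1 peaks (95% exact binomial interval 1.64 to 2.25) and 1.48% of replicate 2 peaks (1.26 to 1.74), against means of 0.0134% and 0.0133% for random placements. The overlap was 5.44% in the quartile of replicate 1 peaks with the lowest fold enrichment and 0.146% in the highest quartile; in replicate 2 these shares were 4.51% and 0.0771%. By q-value the order was the opposite, with 3.23% and 2.56% at a −log10 q of at least 5 and 4.49% and 3.35% at 10. Without chromosome starts the shares of all peaks fell to 0.769% and 0.579%. With 1 knockout library of unknown depth, no test between the genotypes was run.

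The peaks that were called in the knockout lay elsewhere in the genome than most wild-type peaks. Of the 256, 114 (44.5%, 38.3 to 50.8) lay within 500 kb of the first covered base of a chromosome, where 2.15% of replicate 1 peaks and 1.72% of replicate 2 peaks were found. Summits of 9 knockout peaks (3.52%, 1.62 to 6.57) were within 1 kb of an end of a protein-coding gene, against a random mean of 3.47% (one-sided permutation p over random placements = 0.528). Both wild-type lists also had a peak at 151 of the 256 (59.0%, 52.7 to 65.1), against a random mean of 0.351% (one-sided permutation p over random placements = 0.001, the smallest that 1000 placements can give); without chromosome starts the share was 37.3%. The highest fold enrichment in the knockout, 42.0, was at chromosome 10, 72297179 to 72297485, outside protein-coding genes and 357579 bp from Zwint, where replicate 1 had a fold of 89.0 and replicate 2 no peak. The next was a peak inside Gtf2a1l, which encodes a germ-cell counterpart of a general transcription factor subunit (chromosome 17, 88709966 to 88710382), with a fold of 10.9 and no peak in either wild-type list. A peak 17112 bp from Mrgprd had a fold of 9.68 in the knockout and 5.61 and 4.11 in the wild-type replicates. A peak inside a gene and nearest to Hira had a fold of 8.24 in the knockout, 6.50 in replicate 1 and no peak in replicate 2. A peak 8662 bp from Gm45871 had 8.24 in the knockout and 4.36 and 4.26 in the wild-type replicates.

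The wild-type replicates shared most of their strong peaks. Of replicate 1 peaks, 6074 of 8236 (73.7%, 72.8 to 74.7) overlapped a replicate 2 peak, and 5677 of 10371 replicate 2 peaks (54.7%, 53.8 to 55.7) overlapped a replicate 1 peak. Under a reciprocal overlap of at least 50% these shares were 46.9% and 37.2%. Random placements gave means of 0.636% and 0.502% and never more than 0.959% and 0.810% (one-sided permutation p over random placements = 0.001 for each, the smallest possible). When peaks at gene ends were placed at random gene ends, the means were 6.58% and 5.28% and the highest values 7.32% and 5.98%, with the same permutation p. The share found in the other replicate rose with fold enrichment, from 47.2% in the lowest quartile of replicate 1 peaks through 58.8% and 89.5% to 99.5% in the highest, and from 19.7% through 31.1% and 69.2% to 99.0% in replicate 2. Joining overlapping peaks of the replicates gave 5457 shared regions, of which 132 (2.42%, 2.03 to 2.86) had a knockout peak and were left out. The remaining 5325, called ZFP541 regions here, had a median width of 1061 bp and covered 6.62 Mb. Their number depended on the peak threshold, with 2802 regions at a −log10 q of at least 5 and 1594 at a −log10 q of at least 10.

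**Figure D1:**
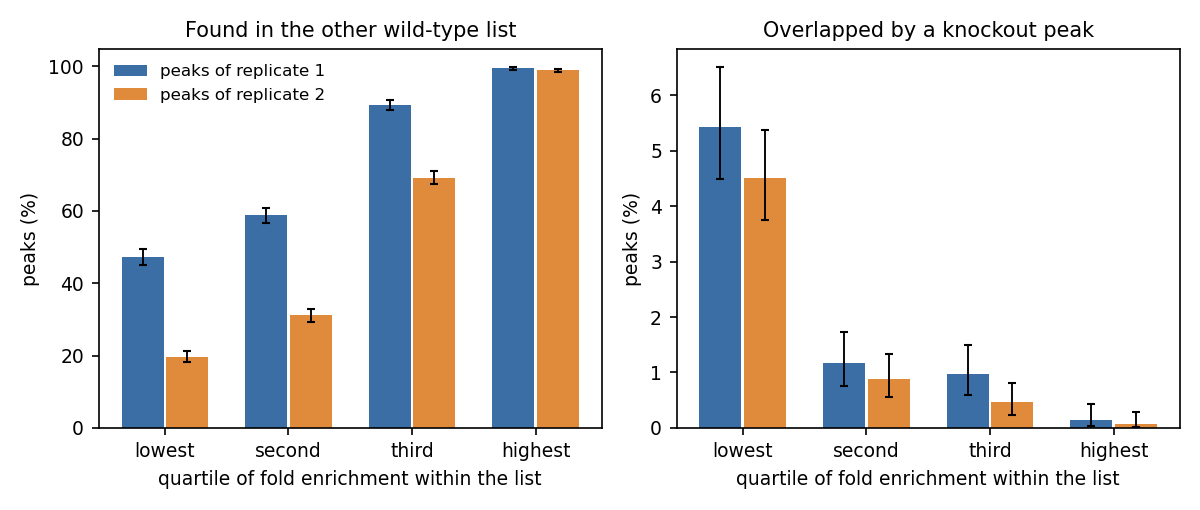
Percent of wild-type peaks found in the other wild-type list (left) and overlapped by a knockout peak (right), by quartile of fold enrichment within each list; bars are shares of peaks of replicate 1 or replicate 2 and error bars are 95% exact binomial intervals. Overlap between replicates reached 99.5% and 99.0% in the highest quartiles, where overlap with the knockout was 0.146% and 0.0771%.

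ZFP541 regions lay mostly at the ends of protein-coding genes. Summits of 3816 regions (71.7%, 70.4 to 72.9) were within 1 kb of a gene end, against a random mean of 3.25% and a highest random value of 4.17% (one-sided permutation p over random placements = 0.001, the smallest possible). A further 1134 summits (21.3%) were inside bodies of protein-coding genes and 375 (7.04%) were outside protein-coding genes, and the median distance from summit to the nearest gene end was 356 bp. Protein-coding genes with a region in the window within 1 kb of either end, called occupied genes here, numbered 4573 of 21779 (21%, 20.5 to 21.5). Of these, 4359 (95.3%) were occupied at 1 end only and 214 at both. The gene table used here has no strand, so a start of transcription could not be told from a gene's other end, and 1994 occupied genes (43.6%) had an end window that overlapped that of another gene. The number of occupied genes depended on the peak threshold, with 2579 at a −log10 q of at least 5 and 1476 at 10.

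**Figure D2:**
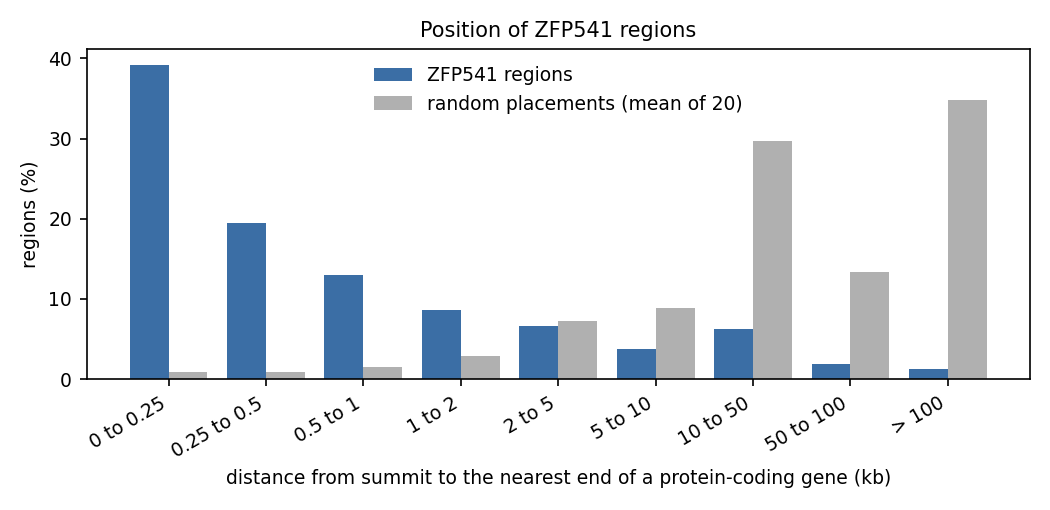
Percent of ZFP541 regions (blue) and of randomly placed regions (grey, mean of 20 placements) by distance in kb from the summit to the nearest end of a protein-coding gene. The first bin, under 0.25 kb, holds 39.2% of ZFP541 regions and 0.859% of random ones.

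Occupied genes were ranked by the mean percentile rank of fold enrichment of their strongest region over the replicates, without regions away from gene ends. Hmga1, which encodes an architectural chromatin protein, had the highest rank among them, with folds of 22.8 and 26.3 in replicates 1 and 2 (chromosome 17, 27554428 to 27558259). Pds5b, a cohesin-associated factor, followed with 22.9 and 23.2 (chromosome 5, 150672998 to 150674703), and Nup210, a nuclear pore protein, with 24.5 and 20.8 (chromosome 6, 91115585 to 91118204). Atp2b1, a plasma membrane calcium pump, had 20.05 and 21.8 (chromosome 10, 98913341 to 98916887). Hacd1 had 23.2 and 19.4 (chromosome 2, 14054860 to 14056751), and Macroh2a1, which encodes a variant histone H2A, had 21.1 and 19.9 (chromosome 13, 56133208 to 56136507). Zfp541 ranked next (chromosome 7, 16061236 to 16062675), before Stox1 with 21.1 and 19.3 (chromosome 10, 62725511 to 62726588). Enoph1 and Hnrnpdl shared 1 region with 17.1 and 23.2 (chromosome 5, 100038163 to 100040990), so which of them it belongs to is open. Hmga1, Zfp541 and Stox1 also had an end window that overlapped that of another gene.

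Among regions whose summit was more than 1 kb from a gene end, the highest rank belonged to one 21436 bp from Tcf12, outside protein-coding genes, with folds of 22.1 and 23.5 (chromosome 9, 72131384 to 72134816). The Nup210 region came next, since its summit was 1455 bp inside that gene although the region reached the end window. A region 40908 bp from Zfp600 and outside protein-coding genes had 23.0 and 20.3 (chromosome 4, 146237567 to 146241715). Regions inside genes near Casz1, a zinc finger gene, had 20.4 and 21.5 (chromosome 4, 148899182 to 148902654), and near Ccdc177, 16.9 and 25.5 (chromosome 12, 80755780 to 80760748).

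Genes encoding histone-modifying enzymes and the HDAC1 and HDAC2 complexes were occupied more often than other protein-coding genes. Of 40 histone modifiers, 22 (55%, 38.5 to 70.7) were occupied, against 20.9% of other genes, with an odds ratio of 4.62 (2.36 to 9.14; two-sided Fisher's exact test, Benjamini-Hochberg adjusted over 16 lists, adjusted exact p = 3.91e-05). The strongest were the histone H3 demethylase genes Kdm4b, with folds of 14.6 and 17.8, and Kdm1a, with 10.0 and 9.66, and the methyltransferase genes Kmt2c (13.6 and 8.02) and Ehmt2 (5.90 and 19.8). Under a reciprocal overlap of at least 50%, Kdm4b, Kdm1a and Kmt2c were not occupied and Ehmt2 was, and the list still passed. In the list of ZFP541, KCTD19 and HDAC1/2 complex members, 11 of 17 (64.7%, 38.3 to 85.8) were occupied, with an odds ratio of 6.91 (2.34 to 22.8; adjusted exact p = 0.000960 by the same test). Besides Zfp541 these included Mideas, which encodes the scaffold of the mitotic deacetylase complex (6.52 and 11.4), the histone-binding Rbbp4 (6.92 and 6.71) and Mta1 (6.17 and 7.55). Ehmt2, Zfp541, Mideas and Rbbp4 had an end window that overlapped that of another gene. Hdac1 had no peak within 1 kb of its ends in any library, but it was occupied with the 2 kb window. At Hdac2, peaks in both replicates (highest folds 5.36 and 3.69) did not overlap each other, although it was occupied in each replicate alone. Kctd19, whose product binds ZFP541, had a peak of fold 2.66 in replicate 1 only. Neither Hdac2 nor Kctd19 therefore counted as occupied. At a −log10 q of at least 10 neither list passed (odds ratios 2.93, adjusted exact p = 0.269, and 1.84, adjusted exact p = 0.963), and without genes that share an end window the complex list did not (6.31, adjusted exact p = 0.166). The odds ratio of the complex list was 15.1 with replicate 1 alone and 6.24 with replicate 2 alone.

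Regulators of transcription in pachytene and later spermatogenesis lay at the threshold. Of 16, 8 (50%, 24.7 to 75.3) were occupied, with an odds ratio of 3.77 (1.23 to 11.5) and an adjusted exact p of 0.0505 by the same Fisher's exact test. After Zfp541, which is in this list too, the strongest were Ovol1 (10.4 and 6.89), the TFIID subunit gene Taf4b (5.45 and 7.05) and Mybl1, which encodes a driver of pachytene transcription (4.64 and 6.38). Zfp541 and Ovol1 had an end window that overlapped that of another gene. The list passed in replicate 1 alone (4.14, adjusted exact p = 0.0273) and in replicate 2 alone (5.72, adjusted exact p = 0.00412). It also passed, at 3.79 and an adjusted exact p of 0.0490, with 108 protein-coding gene entries that carry scaffold coordinates, which were left out as misplaced only after the list results with them had been seen.

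Lists of genes of meiotic prophase, of germ cell development and of the cell cycle were not called higher or lower by this test. Their odds ratio intervals were wide, such as 0.0634 to 2.56 for axis genes and 0.661 to 4.34 for spermatogonial and meiotic entry genes. A difference is therefore not excluded. Meiotic recombination had 8 of 32 occupied (odds ratio 1.25, adjusted exact p = 0.759), led by the helicase gene Hfm1 (12.9 and 11.7), Tex15 (10.0 and 12.2), Zcwpw1 (8.93 and 9.06) and Rec114 (7.71 and 9.73); in replicate 2 alone this list passed at an odds ratio of 2.95 (adjusted exact p = 0.0102). Of 15 axis, cohesin and synaptonemal complex genes, 2 were occupied (0.579, adjusted exact p = 0.801): Sycp1, which encodes the transverse filament of the synaptonemal complex, at 22.1 and 11.8, and Smc3 at 5.71 and 7.05. Spermatogonial and meiotic entry genes had 8 of 25 (1.77, adjusted exact p = 0.430), with Bhmg1, also known as Meiosin, at 10.4 and 16.3, then Id4 (6.78 and 7.05), Dazl (6.79 and 4.12) and Foxo1 (5.71 and 4.50). The piRNA pathway had 7 of 22 (1.76, adjusted exact p = 0.430), led by Tdrd5 (8.57 and 4.70), Spocd1 (6.43 and 5.70), Btbd18 (6.07 and 5.04) and Henmt1 (5.0 and 6.04). Genes of sex chromosome silencing and DNA damage signalling had 6 of 20 (1.61, adjusted exact p = 0.650), led by Rnf8 (9.29 and 8.74), H2ax (7.31 and 9.83), Senp6 (7.83 and 5.37) and Atm (4.09 and 5.30). G2/M and division genes had 6 of 30 (0.941, adjusted exact p = 1), led by the cyclin gene Ccna2 (15.4 and 10.8), Cdc25a (8.57 and 7.72), Cks2 (8.13 and 5.03) and Hspa2 (7.86 and 4.23). Spermiogenesis genes had 5 of 30 (0.752, adjusted exact p = 0.801), led by Catsper2 (7.35 and 7.38), Tssk6 (6.48 and 7.05), Odf2 (5.24 and 5.71) and Izumo1 (4.93 and 5.43). Izumo1 was not occupied by replicate 1 peaks alone, at either stricter q-value, under reciprocal overlap or with the 500 bp window. Other genes named here lost occupancy too, such as Dazl, Foxo1, Atm, Hspa2 and Henmt1 at both stricter q-values. Cks2 and Henmt1 lost it under reciprocal overlap and Ccna2 with the 500 bp window. Zcwpw1, Rec114, Bhmg1, Btbd18, H2ax, Atm, Ccna2, Cks2, Catsper2, Tssk6 and Izumo1 had an end window that overlapped that of another gene. The Zcwpw1 and Izumo1 regions lay outside these genes.

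Housekeeping and non-germline lists did not pass either. Ribosomal protein genes had 10 of 42 occupied (1.18, adjusted exact p = 0.801), among them Rpl7 (12.1 and 8.06), Rps19 (7.73 and 6.64) and Rpl10a (6.79 and 4.27). The odds ratio of this list was 1.79 with replicate 1 alone and 1.04 with replicate 2 alone. DNA replication genes had 5 of 32 (0.696, adjusted exact p = 0.801), led by the licensing factor gene Cdt1 (9.42 and 10.7), Mcm9 (6.07 and 6.88), Rfc5 (4.88 and 6.40) and Pcna (3.21 and 3.62). Proteasome genes had 3 of 32 (0.389, adjusted exact p = 0.344), which were Psma7 (5.36 and 9.06), Psmc2 (4.88 and 3.02) and Psmd11 (5.0 and 2.91). Of 20 genes of Sertoli, Leydig and peritubular cells, 2 were occupied (0.418, adjusted exact p = 0.505): Amh, the anti-Müllerian hormone gene, at 11.4 and 12.1, and Inha at 3.71 and 7.05. Both genes had an end window that overlapped that of another gene, and the Inha region lay outside Inha. The same overlap of windows held for Rpl7, Rpl10a, Cdt1, Rfc5, Pcna, Psma7 and Psmc2, and the Rpl7 region lay outside Rpl7. Amh was not occupied under reciprocal overlap, and Inha was not at either stricter q-value or with the 500 bp window. None of 15 blood, immune and endothelial genes (exact interval 0 to 21.8%, adjusted exact p = 0.168) and none of 18 hepatocyte genes (0 to 18.5%, adjusted exact p = 0.0812) was occupied. The hepatocyte list passed as lower in replicate 1 alone (adjusted exact p = 0.0449) and in replicate 2 alone (adjusted exact p = 0.0192), and the blood list in replicate 2 alone (adjusted exact p = 0.0440).

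**Figure D3:**
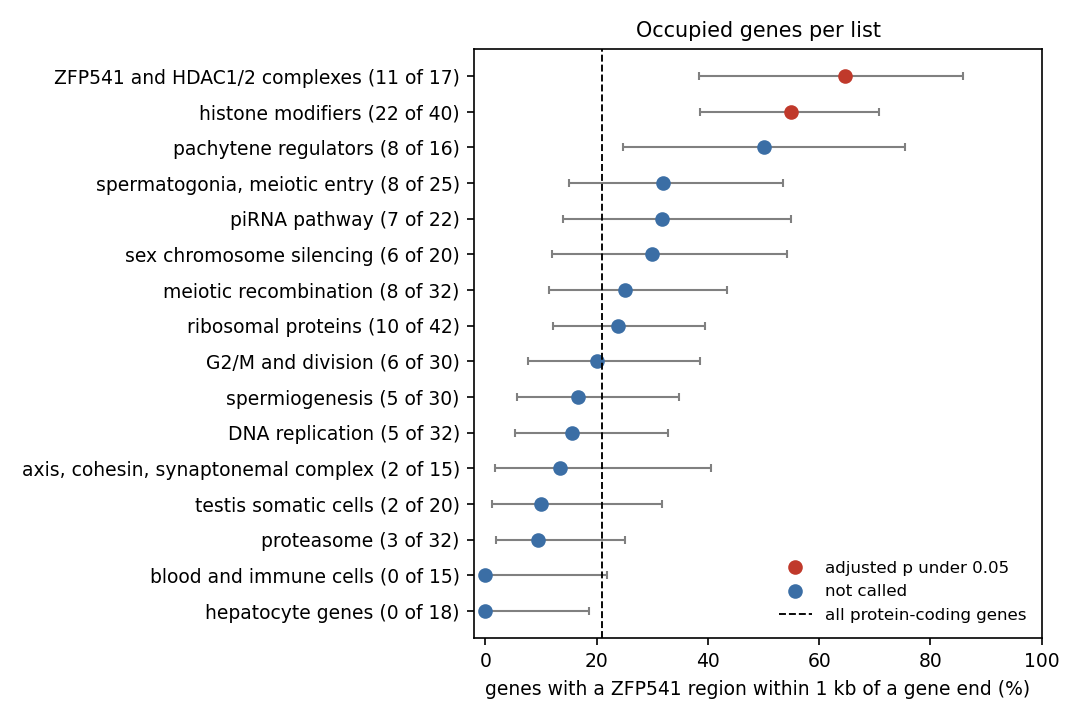
Percent of genes with a ZFP541 region within 1 kb of a gene end, for each of 16 lists with the number of occupied and listed genes; points are shares, bars are 95% exact binomial intervals, and the dashed line marks all protein-coding genes (21%). Red points mark the 2 lists with an adjusted p under 0.05, histone modifiers at 55% and ZFP541 and HDAC1/2 complexes at 64.7%.

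The comparison of the X chromosome with autosomes bears on the sex chromosomes, which are transcriptionally silenced in pachytene. On the X, 26 of 963 protein-coding genes (2.70%, 1.77 to 3.93) were occupied, against 4547 of 20560 autosomal genes (22.1%, 21.6 to 22.7), an odds ratio of 0.0977 (0.0634 to 0.144; two-sided Fisher's exact test, p = 3.05e-66). The lowest autosome was chromosome 7 with 14.5% and the highest chromosome 12 with 27.4%. The X had 0.232 regions per Mb and the autosomes 2.19, ranging from 1.44 on chromosome 1 to 3.53 on chromosome 11. At a −log10 q of at least 10 the odds ratio was 0.0269, with 2 occupied X-linked genes. The occupied X-linked genes were led by Lonrf3 (9.64 and 9.06) and included the histone methyltransferase gene Suv39h1 (5.0 and 6.04), the HDAC complex gene Rbbp7 (5.36 and 6.71) and the TFIID-related Taf7l (3.93 and 4.03). Of these, Rbbp7 had an end window that overlapped that of another gene. None of the 256 protein-coding genes on the Y was occupied. Genes are not replicates, so these tests describe the 3 libraries.

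**Figure D4:**
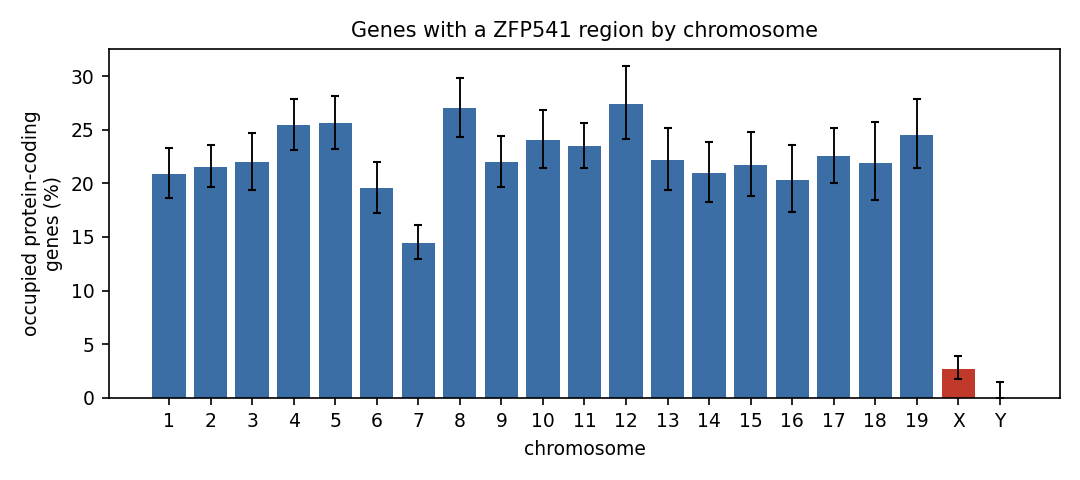
Percent of protein-coding genes with a ZFP541 region within 1 kb of a gene end, by chromosome; bars are shares and error bars are 95% exact binomial intervals. The X (red) is at 2.70%, below the lowest autosome, chromosome 7, at 14.5%, and the Y is at 0.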

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

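The alternatives on the knockout list's −log10 p, placement at gene ends, chromosome starts, clustered families, shared windows and scaffold entries were chosen after seeing the data. Overlap of the replicates, overlap with the knockout, the share of regions at gene ends and the low occupancy of the X kept their direction and stayed past the threshold under every alternative run for them. The number of ZFP541 regions, 5325, became 2802 at a −log10 q of at least 5 and 1594 at 10, and with 1 replicate alone it was 8077 to 10217, since fewer or more peaks then qualify. The 2 lists past the threshold became 0 at a −log10 q of at least 10 (Fisher's exact test; 1 list had an unadjusted p under 0.05), 1 without shared windows, 3 with scaffold entries kept and 4 to 6 with 1 replicate alone; apart from these counts the cause was not tested. Over 192 pairs of a list and an alternative, 167 kept direction and side of the threshold, 3 lost the call, 7 gained it and 15 turned direction, none of them past the threshold. At a −log10 q of at least 5 the odds ratios that turned were 1.15 for axis genes, 0.744 for the piRNA pathway, 0.783 for ribosomal genes and 0.647 for spermatogonial genes. At 10 they were 0 for the piRNA pathway and 0.687 for ribosomal genes, and with a reciprocal overlap 0.875 for the piRNA pathway. Without clustered families they were 0.887 for recombination and 0.951 for ribosomal genes, without shared windows 1.58 for axis genes and 0.995 for ribosomal genes, and with the 2 kb window 1.06 for G2/M genes. With replicate 1 alone they were 1.17 for axis genes (0.649 with replicate 2 alone) and 1.17 for G2/M genes (0.790 with replicate 2 alone). With replicate 2 alone the value that turned was 1.56 for DNA replication genes (0.901 with replicate 1 alone). The cause of these turns was not tested. Of 710 pairs of a named gene and an alternative, 65 changed between occupied and not, 27 of them at a −log10 q of at least 10. Summit and reciprocal overlap used 100 placements in place of 1000. The alternative sets of start sites and all alternatives for CpG content and enriched short sequences were not run. No paired analysis was possible because the ChIP groups compared share only 1 replicate number. Unknown depth limits what a missing peak shows, above all in the knockout.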

Other observations

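In this part, the tests on symbol families and gene classes, the matched-fold X test, the comparison with ribosomal, proteasome and replication genes and all tests on knockout peaks were chosen after the results were seen. Genes were grouped by the stem of their symbols, keeping stems with at least 20 genes. Over all 112 stems, two-sided Fisher's exact tests with Benjamini-Hochberg adjustment called 11 higher and 27 lower than other genes. Outside clustered families, 81 stems were tested in the same way against genes outside such families; 3 were occupied more often than other genes and 3 less often. Higher were Zbtb, the BTB zinc finger genes, with 21 of 41 (51.2%, adjusted exact p = 0.00718), Ube, mostly ubiquitin-conjugating enzymes, with 20 of 42 (47.6%, adjusted exact p = 0.0287), and Map, a stem shared by kinases and microtubule proteins, with 21 of 47 (44.7%, adjusted exact p = 0.0449). Lower were Cd, mostly cell surface antigens, with 4 of 99 (4.04%, adjusted exact p = 4.54e-06), Il, interleukins and their receptors, with 6 of 83 (7.23%, adjusted exact p = 0.00211), and Col, mostly collagens, with 1 of 44 (2.27%, adjusted exact p = 0.00211). Genes of clustered families were occupied in 4.92% of cases and the others in 24.7%. The stem Gm held 93 of the 202 occupied genes of clustered families.

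Long non-coding RNA genes were occupied in 6.50% of cases (6.08 to 6.95), and in 1.29% where they lay away from ends of protein-coding genes. The Y held 32 ZFP541 regions with median folds of 4.46 and 4.36, none at or inside a protein-coding gene. Peaks found in 1 replicate only also lay at gene ends more often than random placements did, in 35.8% of 2162 peaks of replicate 1 and 36.0% of 4694 of replicate 2 (random means 3.23% and 3.26%).

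The low occupancy of X-linked genes has a technical candidate in the single X of male cells, which could halve its signal. The test first written compared X-linked genes with any region with autosomal genes whose region had at least 2 times the median fold, and its odds ratio of 0.673 had an interval that reaches 1 (0.435 to 1.00; exact p = 0.0498), so it leaves this open. It was then replaced by a comparison with X-linked genes whose region had at least the median fold. That comparison gave 0.462 (0.271 to 0.739, two-sided Fisher's exact test, p = 0.000428) and was chosen after the first value. These tests assume that fold falls with the signal. Fold is a ratio over the caller's background, which could fall on the X too. The control of each peak call is not given, so the tests cannot decide whether the single X is the cause. Clustered families on the X do not account for the pattern, since the odds ratio without them was 0.105. No biological explanation was tested, and sequence content and mappability of the X stay open.

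Histone modifiers and HDAC1/2 complex genes, 57 together, were occupied in 57.9% of cases. Clustered families in the background do not account for this, with a pooled odds ratio of 4.08 (2.33 to 7.25) without them, and neither does gene length, since the share lay at percentile 100 of 10000 length-matched lists, whose highest value was 49.1%. The 106 ribosomal, proteasome and replication genes were occupied less often, with an odds ratio of 6.72 (3.05 to 14.9) for the lists against them; they were picked after their values were seen, and broadly used genes in general stay open. Both calls end at a −log10 q of at least 10, and CpG content, which was not tested, may still contribute. No biological explanation was tested.

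Peaks called in the knockout may come from ZFP541 left in those cells or from sequence present in more copies than the reference holds. Remaining binding would place them at gene ends, where 3.52% of them lay against 59.3% and 54.0% of all peaks of the wild-type replicates. Extra copies raise reads in ChIP and control alike and so give a high −log10 p for a given fold; a first comparison of this ratio between the knockout and wild-type libraries is not used, since it depends on depth and on the lowest −log10 p of each list. It was replaced by a comparison within each wild-type library among peaks with a −log10 p of at least 4.47. Its intervals come from a bootstrap within a library and do not cover variation between libraries. The median ratio at sites of knockout peaks near chromosome starts was 3.16 times (2.81 to 4.797) and 2.76 times (2.42 to 4.52) that of peaks in ZFP541 regions. At the other sites it was 7.22 times (5.31 to 9.27) and 6.73 times (4.24 to 9.42). The ratio combines a low fold and a high −log10 p, which were already seen at these sites, and the control of each peak call is not given in the sources used here, so extra copies stay open, as does the origin of the 78 knockout peaks in neither wild-type list.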
